A study of Mus musculus with 5 samples.

How the data were processed

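PU.1 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on conventional dendritic cells (cDCs) and plasmacytoid dendritic cells (pDCs) that had been grown in Flt3L culture. There were 4 PU.1 libraries, 2 biological replicates per cell type, and 1 input library of unprecipitated chromatin from cDCs. Per the labels' protocols, cells were crosslinked with paraformaldehyde, chromatin was sonicated, and PU.1 was precipitated with the T-20 antibody. Single-end reads of 49 bp were sequenced on an Illumina HiSeq 2000.

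The values are read counts per genomic window as deposited, with no normalisation. Per the submitters' processing notes, Subread 1.4.4 was used and the genome build was mm10. Which step of the work Subread did, how reads were extended or filtered, and how the windows were chosen are not given in the sources used here. The deposited counts cover 329996 windows, each 10 bp wide and starting on a 50 bp grid. The smallest sum over the 5 libraries was 33 counts, so only windows with that much signal are listed, and 79.4% of windows lie 50 bp after another one. A read can therefore be counted in several neighbouring windows, and the total over windows is not the sequencing depth, which is unknown. The counts of each sample were checked against the deposited table of the whole series, and all 5 columns were equal.

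Totals over windows were 11034858 and 11388554 counts for cDC replicates 1 and 2, 8099633 and 6896416 for pDC replicates 1 and 2, and 2776490 for the input. The pDC folds are thus the less precise side of each comparison. A set of 146 windows had at least 1000 input counts and lay mostly in 2 short stretches, on chromosome 14 between 19415651 and 19419760 (70 windows) and on chromosome 2 between 98662351 and 98667410 (46 windows). These are called repeat windows here. They held 74.6% of the input counts, 10.5% and 9.15% of the counts of cDC replicates 1 and 2, and 10.1% and 18.0% of those of pDC replicates 1 and 2.

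Replicates were compared before use. Over windows with at least 20 counts in a replicate pair, the mean chi-square per window was 1.40 for the cDC pair and 2.16 for the pDC pair, where counting error alone gives a value near 1, so no library was a copy of another.

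Groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Windows were kept with the filterByExpr function of edgeR at a minimum count of 10, which left 286435 windows and removed 43561. The pDC and cDC libraries were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM factors, cell type as the only term and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.159. Log2 folds are pDC minus cDC, and the standard error (SE) printed beside a log2 fold is the one implied by the test's F statistic. CPM values are counts scaled to the TMM-adjusted library sizes. With 2 libraries against 2, the smallest two-sided p that an exact permutation test can give is 0.333, so no single value was tested on its own.

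Windows at most 100 bp apart were joined into regions, split at 5000 bp, and the window p-values of a region were combined by the Simes method. The direction of a region is that of its window with the smallest p. Genes were taken from RefSeq annotation of GRCm38.p6, whose chromosome coordinates are those of mm10, with GenomicRanges 1.54.1. It was used as a table of 21883 protein-coding genes with start and end but no strand, exon or UTR. A gene locus was therefore the gene span plus 10 kb on both sides, in place of the planned gene span plus 10 kb upstream, and the signal of a locus was the sum of its tested windows. A position is described only as inside the gene span or by its distance from it. Tested windows fell in the loci of 14998 genes. A window could count for several genes: the median locus shared 50% of its windows with another gene, and 5780 loci shared all of them.

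The 15 gene lists, written from textbook knowledge, were compared on the log2 CPM of locus sums (prior count 2) with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists. They cover cDC and pDC identity, dendritic cell regulators, known PU.1 targets, MHC class II and class I presentation, Toll-like receptor and interferon sensing, C-type lectins, chemokine receptors, markers of B cells, of T and NK cells, of macrophages and neutrophils and of erythroid, megakaryocyte and mast cells, non-haematopoietic genes and housekeeping genes. PU.1 signal over the input was tested in a fit of all 5 libraries with library sizes set to the totals over windows, and a window counted as above input at an adjusted p below 0.05 and a fold of at least 2. In that fit the single input was assumed to vary like the PU.1 libraries, and the input of cDCs also served for pDCs.

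Genes are named by 4 rules. The first is a list of dendritic cell and myeloid genes named whatever their values. The second takes, in each direction, the 10 called loci with the largest fold, a mean of at least 30 counts, both libraries of one cell type above both of the other, and at least 1 window not shared with a gene already taken. The third takes up to 4 members of each list with the smallest p. The fourth takes the 5 windows per direction with the smallest adjusted p. Other list members named are called out as chosen after their values were seen.

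The fits that compare pDCs with cDCs were tested on simulated counts made from the real means and library sizes. The fit over the input was not simulated. Of simulated 2-fold changes, 7.5% were recovered among 286435 windows, 10% among 60527 regions and 64% among 14998 gene loci. Of 4-fold changes, 68.9%, 74% and 100% were recovered in the same order. Of unchanged items, 20 of 285508 windows, 4 of 60327 regions and 3 of 14758 loci were called. Windows and loci were drawn independently, with a dispersion of 0.025 for windows and 0.0225 for loci. In each simulation 200 regions or loci were changed, besides a list of 40 loci shifted together. In the data 14.4% of windows were called, neighbouring windows can share reads and the pDC pair varied more than the cDC pair. The shares recovered and falsely called therefore need not hold in the data.

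Alternatives were library-size scaling, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter and stricter filters, all 5 libraries in 1 fit, a replicate block, abundance-trended offsets, a minimum fold of 1.5, each library left out, other locus definitions, a wider region gap, and other scalings and thresholds for the input. Alternatives added after seeing the data concern the repeat windows, loci by nearest gene span within 50 kb, loci by gene span only, the lists with each library left out, and a Fisher test of the direction of list members. No genome sequence was used here, so sequence motifs, GC content and loci around transcription start sites were not analysed, and scaling on background bins was not run because only selected windows are listed. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.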

Results

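PU.1, the ETS-family transcription factor encoded by Spi1, was mapped by ChIP-seq in 2 kinds of mouse dendritic cell grown in Flt3L culture from a strain labelled C56BL/6. Conventional dendritic cells (cDCs) take up antigen and present it to T cells, and plasmacytoid dendritic cells (pDCs) are known for type I interferon production. Each cell type had 2 biological replicates, and the only input library came from cDCs. Read counts covered 329996 windows of 10 bp, with totals over windows between 6896416 and 11388554 counts in the PU.1 libraries and 2776490 in the input. The comparison asked where PU.1 signal differed between pDCs and cDCs. Every log2 fold below is pDC minus cDC with its SE, n = 2 libraries per cell type, and positions are in mm10.

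PU.1 signal differed between pDCs and cDCs around single genes known from each cell type, but most loci of the 2 identity lists were not called. Of 39 cDC identity loci, 13 were higher in cDCs, 3 in pDCs and 23 were not called. For 38 pDC identity loci, 11 were higher in pDCs, 2 in cDCs and 25 were not called. Over all loci 17.6% were called. No gene list as a whole passed by camera (5 of 15 with an unadjusted p below 0.05, smallest adjusted p 0.0674). With an estimated correlation, a version with little power at 4 libraries, the smallest camera adjusted p was 0.632. By fry 1 list passed, the B cell markers. At Siglech, a surface lectin of mouse pDCs, the summed signal of the locus was 1.78-fold higher in pDCs, and at Dntt, the DNA nucleotidyltransferase of lymphoid progenitors, it was 4.17-fold higher. At Zfp366, which encodes the zinc-finger protein DC-SCRIPT, it was 1.67-fold higher in cDCs, and at H2-Eb1, an MHC class II gene, 2.56-fold higher. Tested against a minimum fold of 1.5, the calls of Siglech and Zfp366 ended (edgeR adjusted p = 0.1615 and 0.4735). By the gene span alone, a locus definition chosen after seeing the data, the Dntt call ended (log2 fold 0.43, edgeR adjusted p = 0.548). The Spi1 locus itself was not called different, with a log2 fold of -0.11 ± 0.11 (edgeR adjusted p = 0.549).

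Of 14998 gene loci with signal, 1406 were higher in pDCs and 1239 in cDCs, with median log2 folds of 0.93 and -0.85. Loci called in either direction made up 17.6% of all, the share to hold beside the list counts below. By window, 22882 of 286435 were higher in pDCs and 18229 in cDCs, and 7671 and 5386 of these differed by more than 4-fold. Joined into 60527 regions with a median width of 210 bp, 5123 were higher in pDCs and 3634 in cDCs. Windows were also binned by mean count, without scaling to library size. In the lowest 50%, 10349 were higher in pDCs and 5812 in cDCs, and between 50 and 90% 10006 and 9983. Between 90 and 99% the numbers were 2288 and 2342, and in the top 1% 239 and 92. The excess of windows higher in pDCs thus lay mostly in the lowest bin. At a mean of at least 30 counts, 7403 windows and 833 loci were higher in pDCs, and 8315 windows and 881 loci in cDCs. The cDC libraries had the larger totals. At the same CPM level and fold, a window higher in pDCs therefore has a lower mean count than one higher in cDCs. The bins and the limit of 30 counts thus cannot separate signal strength from library size, whose share was not tested. The balance of directions also depended on scaling. With library-size scaling in place of TMM, 18506 windows were higher in pDCs and 24740 in cDCs, and for regions the split was 4218 to 5057. For loci the split kept its side, at 1347 to 1246. The median log2 fold of all windows moved from 0.01 to -0.11. With library sizes taken from the repeat windows, a scaling chosen after seeing the data, the median of all windows moved to -0.54 and that of all loci to -0.46. Then 3833 windows and 30 loci were higher in pDCs, and 16723 windows and 75 loci higher in cDCs. Of 92 called loci named by rule or afterwards, 67 lost their call under that scaling and 3, Stat5b, Coro1a and Vav1, changed sign without a call. The 3 sign changes go with the common shift of all loci. That scaling also set the pDC replicates apart. Replicates 1 and 2 had 817060 and 1239815 counts in the repeat windows, but 7282573 and 5656601 outside them. How many calls were lost through that spread was not tested. Against a minimum fold of 1.5, 63 of the 92 lost their call.

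The number of calls also depended on single libraries. The 41111 differing windows became 12511 without cDC replicate 1, 15595 without cDC replicate 2, 23748 without pDC replicate 1 and 67073 without pDC replicate 2. The 8757 differing regions became 3031, 3644, 5710 and 15662 in the same order, and the 2645 differing loci became 883, 1131, 3169 and 5402.

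Signal correlated more closely within than between cell types, a difference that was not tested. Across 286290 windows, which are not independent replicates, Pearson's correlation of log2 CPM was 0.896 between the cDC replicates and 0.796 between the pDC replicates, and Spearman's was 0.861 and 0.759. Between cell types, pDC replicate 1 had Pearson's correlations of 0.579 and 0.598 with cDC replicates 1 and 2, and pDC replicate 2 had 0.677 and 0.702. Those of the input with the PU.1 libraries lay between 0.0245 and 0.0710.

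Among regulators of dendritic and myeloid cell development, 5 of 26 loci were higher in pDCs, 2 were higher in cDCs and 19 were not called, with 5 and 2 also when adjusted over the list alone. Spib, an ETS factor of pDCs and B cells (chromosome 7, 44525995 to 44532087), had a log2 fold of 1.34 ± 0.20 (edgeR adjusted p = 0.000555). Its called region lay 2.46 kb outside the gene span, and all windows of the locus are shared with neighbouring genes. Irf4, an interferon regulatory factor of B cells and of some cDCs (chromosome 13, 30749233 to 30766981), had a log2 fold of 1.01 ± 0.20 (edgeR adjusted p = 0.00392), with a called region 4.52 kb outside the gene span. Zeb2, a transcriptional repressor that acts in pDC development (chromosome 2, 44983512 to 45117442), lay at 0.54 ± 0.13 (edgeR adjusted p = 0.0114). Cebpb, a CCAAT/enhancer-binding protein of myeloid cells, lay at 1.25 ± 0.28 (edgeR adjusted p = 0.00671). On the cDC side, Zfp366 (chromosome 13, 99184823 to 99247032) had a log2 fold of -0.74 ± 0.14 (edgeR adjusted p = 0.00325), with 129 and 135 CPM in the cDC libraries and 75.7 and 82.7 CPM in the pDC libraries. Bcl6 (-0.50 ± 0.14) and Stat5b (0.36 ± 0.12), named after their values were seen, complete the called regulators. The calls of Zeb2, Bcl6 and Stat5b ended without cDC replicate 1, at log2 folds of 0.54, -0.57 and 0.31. They also ended without cDC replicate 2, at 0.54, -0.42 and 0.41. Cebpb lost its call without cDC replicate 1 (0.97) and Zfp366 without cDC replicate 2 (-0.70). The Irf4 value belongs to the locus with its flanks of 10 kb, since it turned to -0.08 with flanks of 50 kb and to -0.12 when each window was given to its nearest gene, an assignment chosen after seeing the data. The Spib call was lost by nearest gene (0.85, edgeR adjusted p = 0.340) and by the gene span alone (0.83, edgeR adjusted p = 0.325), a definition also chosen after seeing the data, and Spib lay at 0.56 with flanks of 50 kb. By the gene span alone the calls of Irf4 (0.45), Zeb2 (0.08), Cebpb (0.35), Bcl6 (-0.13) and Stat5b (0.35) ended as well. Cebpb also lost its call at a mean of at least 30 counts (0.46) and at 2-fold over input (0.76). Stat5b lost it by nearest gene, with library-size scaling, no filter, both stricter filters, all 5 libraries and the DESeq2 Wald test, at log2 folds between 0.34 and 0.39.

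Other genes named whatever their values were not called as whole loci. Irf8, which cDC subsets and pDCs express, lay at -0.03 ± 0.13, Tcf4, the E protein of pDC identity, at 0.06 ± 0.12, and Bcl11a at -0.03 ± 0.11. Runx2 lay at -0.22 ± 0.11, Batf3 at -0.24 ± 0.15, Id2 at -0.64 ± 0.25, Zbtb46 at -0.25 ± 0.10 and Nfil3 at 0.17 ± 0.19. The receptor genes Flt3 (-0.25 ± 0.12) and Csf1r (0.29 ± 0.12) and the integrin gene Itgax (-0.11 ± 0.13) were not called either. Their edgeR adjusted p lay between 0.0913 for Id2 and 0.916 for Irf8. Without pDC replicate 2 the log2 fold was -0.97 for Id2, -0.33 for Runx2 and 0.36 for Csf1r. It was -0.29 for Zbtb46, -0.30 for Flt3 and -0.36 for Batf3. These loci gained a call in that fit, which holds no spread between pDC libraries. With flanks of 50 kb Irf8 lay at 0.32, higher in pDCs (edgeR adjusted p = 0.0457), and Batf3 at -0.56 and Id2 at -0.55, higher in cDCs (edgeR adjusted p = 0.00526 and 0.0498). Csf1r passed towards pDCs at a mean of at least 30 counts and at 2-fold over input (edgeR adjusted p = 0.0285 and 0.0448), and Zbtb46 towards cDCs at 2-fold over input (0.0449). Single regions differed within several uncalled loci. A region in the Irf8 span (chromosome 8, 120750701 to 120750960) was higher in pDCs, with a log2 fold of 1.34 ± 0.33 at its best window (edgeR adjusted p = 0.0116 for the region). Flt3 held a region higher in cDCs (chromosome 5, 147351951 to 147352260) at -1.52 ± 0.32, and Csf1r one higher in pDCs (chromosome 18, 61120601 to 61120910) at 1.43 ± 0.27, with edgeR adjusted p of 0.00644 and 0.00311 for the regions.

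**Figure D1:**
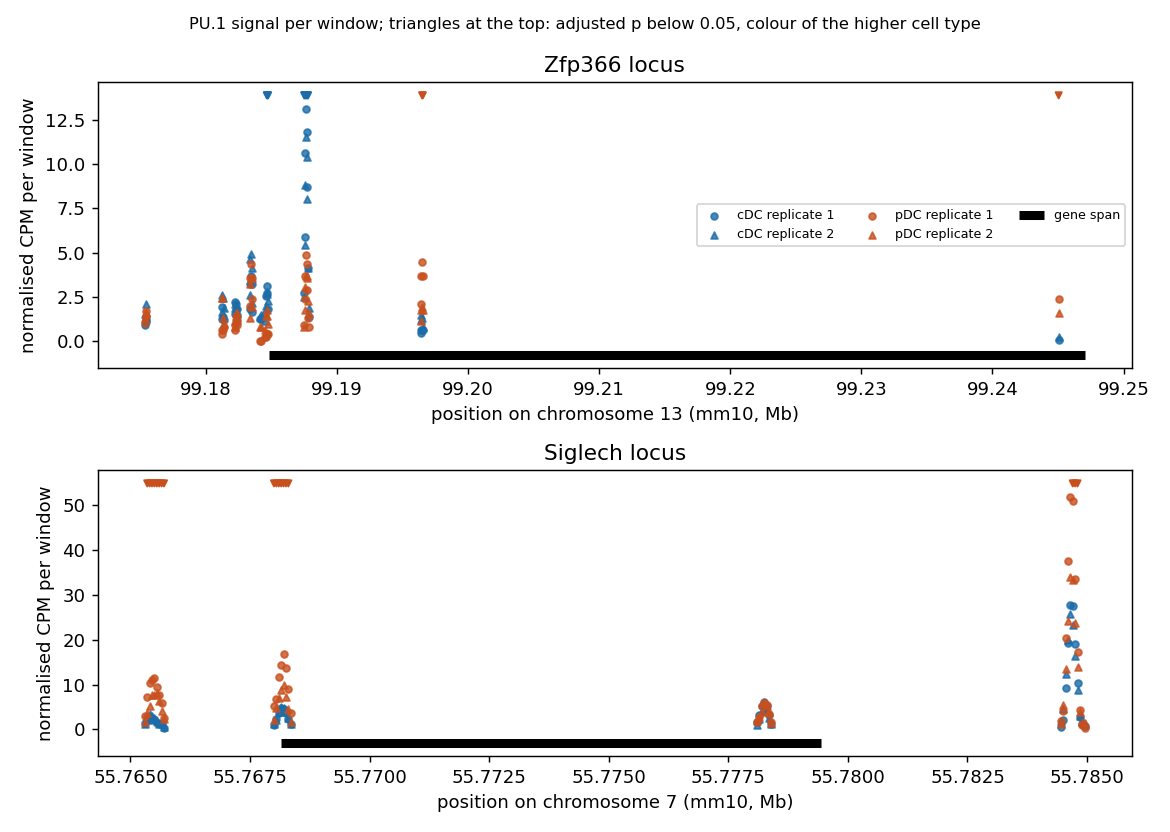
Normalised CPM of each tested window (y axis) by position on the chromosome in Mb (x axis) at Zfp366 and Siglech, with 1 point per window and library (circles replicate 1, triangles replicate 2, cDCs blue, pDCs orange), the gene span as a black bar, and triangles along the top edge where a window had an adjusted p below 0.05, in the colour of the higher cell type. At Zfp366 the strongest windows, around 99187651, are higher in cDCs and weaker windows around 99196551 and 99245051 are higher in pDCs, and at Siglech windows around 55765551 and 55768201 are higher in pDCs, as are some of the strongest, near 55784651, whose own log2 fold was 0.69 without a call.

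Of 39 measured cDC identity loci, 13 were higher in cDCs, 3 were higher in pDCs and 23 were not called, and adjusted over the list alone 14 and 4 were called. Anpep, the aminopeptidase CD13 (chromosome 7, 79821803 to 79848210), had a log2 fold of -1.55 ± 0.26 (edgeR adjusted p = 0.00132), with 61.8 and 66.9 CPM in cDCs against 15.6 and 28.9 CPM in pDCs. Gcsam lay at -1.21 ± 0.23 (edgeR adjusted p = 0.00267), with all its windows shared with other genes, and Itgae, the integrin chain CD103, at -0.79 ± 0.15 (edgeR adjusted p = 0.00289). In the other direction, Tbc1d8 lay at 0.75 ± 0.13 (edgeR adjusted p = 0.00157) and the lectin gene Clec10a at 1.18 ± 0.23 (edgeR adjusted p = 0.00304), and the third was Irf4. The Gcsam call was lost when only windows with a mean of at least 30 counts were used (-0.54, edgeR adjusted p = 0.282), and Clec10a lay at -0.06 with flanks of 50 kb. Clec10a also lost its call by the gene span alone (0.59), and Tbc1d8 by nearest gene (0.31).

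Of 38 measured pDC identity loci, 11 were higher in pDCs, 2 were higher in cDCs and 25 were not called, and adjusted over the list alone 13 and 2 were called. Dntt (chromosome 19, 41029275 to 41059525) had a log2 fold of 2.06 ± 0.24 (edgeR adjusted p = 0.000147), with 11.7 and 11.8 CPM in cDCs against 51.9 and 45.7 CPM in pDCs. Its called regions lay 2.57 and 6.92 kb outside the gene span, and by the gene span alone the log2 fold was 0.43 (edgeR adjusted p = 0.548). Ptprf, a receptor tyrosine phosphatase, lay at 1.19 ± 0.17 (edgeR adjusted p = 0.000438) and held 3 regions higher in pDCs. Siglech (chromosome 7, 55768154 to 55779448) lay at 0.84 ± 0.13 (edgeR adjusted p = 0.000917), with regions higher in pDCs at an end of the gene span (55768001 to 55768360) and 2.59 kb outside it. Spib and Zeb2 are also members. Pacsin1 (-1.39 ± 0.34) and Fcrla (-0.69 ± 0.19), named after their values were seen, were higher in cDCs. Both calls ended without cDC replicate 1, at -1.38 and -0.72, and without cDC replicate 2, at -1.39 and -0.66. Pacsin1 also lost its call with flanks of 50 kb (-0.36) and with no filter (-0.67), and Fcrla by the gene span alone (-0.26).

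**Figure D2:**
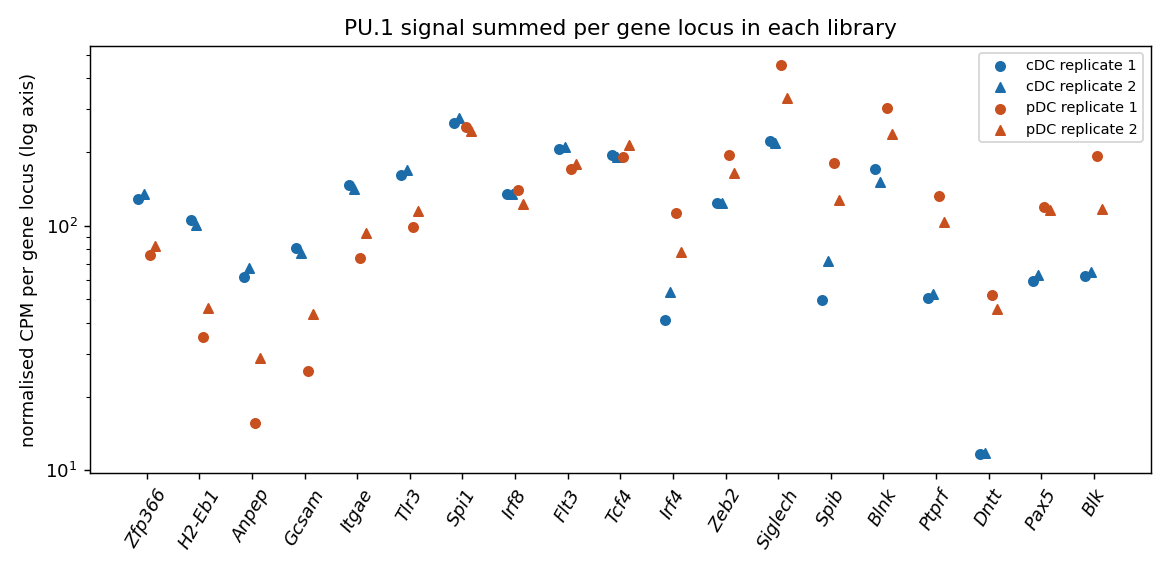
PU.1 signal summed per gene locus in normalised CPM (y axis, log scale) at 19 named loci (x axis) for each of the 4 PU.1 libraries, with cDCs in blue, pDCs in orange, circles for replicate 1 and triangles for replicate 2. Dntt has 11.7 and 11.8 CPM in cDCs against 51.9 and 45.7 CPM in pDCs, and Anpep 61.8 and 66.9 CPM in cDCs against 15.6 and 28.9 CPM in pDCs.

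MHC class II presentation loci were higher in cDCs in 4 of 18 cases and higher in pDCs in 0, and adjusted over the list alone in 5 and 1. H2-Eb1 (chromosome 17, 34305867 to 34316674) had a log2 fold of -1.36 ± 0.18 (edgeR adjusted p = 0.000307) and held 4 regions higher in cDCs, among them 34308201 to 34308410 within its span. Over all settings its log2 fold lay between -1.89 and -0.42. H2-Ab1 (-0.52 ± 0.14), H2-Aa (-0.36 ± 0.11) and the costimulatory ligand gene Cd86 (-0.55 ± 0.15) had smaller folds. Their calls ended without cDC replicate 1, at -0.53, -0.34 and -0.49, and without cDC replicate 2, at -0.51, -0.38 and -0.61. At a mean of at least 30 counts the calls of H2-Ab1 (-0.32), H2-Aa (-0.30) and Cd86 (-0.54) were lost, and at 2-fold over input those of H2-Ab1 (-0.26) and H2-Aa (-0.33). H2-Ab1 lost it by nearest gene too (-0.47), and H2-Aa by the gene span alone (-0.07). Among 17 MHC class I and cross-presentation loci, 3 were higher in each cell type, and adjusted over the list alone 5 were higher in pDCs and 3 in cDCs. Tapbpl, a tapasin relative, lay at 0.93 ± 0.16 (edgeR adjusted p = 0.00167), whereas Rab43 (-0.52 ± 0.12) and Wdfy4 (-0.39 ± 0.11), both known from cross-presentation, and the immunoproteasome gene Psmb9 (-0.39 ± 0.12), named after its values were seen, lay on the cDC side. The transporter gene Tap2 lay at 0.52 ± 0.15 on the same windows as Psmb8, also named after its values were seen, so these count as 1 signal. The calls of Rab43, Wdfy4, Psmb9 and Tap2 ended without cDC replicate 1, at -0.48, -0.40, -0.30 and 0.49. They also ended without cDC replicate 2, at -0.56, -0.38, -0.47 and 0.55. With flanks of 50 kb Tap2 turned to -0.36 and Psmb8 to -0.34, both higher in cDCs (edgeR adjusted p = 0.0110 and 0.0167), and the calls of Tapbpl (0.23) and Psmb9 (-0.17) ended. By nearest gene and by the gene span alone Tap2 turned to -0.87 and -0.88 without a call, and calls ended for Tapbpl (0.92 and 0.91) and Psmb8 (0.28 and 0.27). At a mean of at least 30 counts the calls of Rab43 (-0.41) and Wdfy4 (-0.19) ended, and at 2-fold over input that of Wdfy4 (-0.23).

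Toll-like receptor and interferon sensing loci were higher in cDCs in 6 of 29 cases and higher in pDCs in 1, and adjusted over the list alone in 6 and 2. Tlr3, a receptor for double-stranded RNA, lay at -0.64 ± 0.14, Tlr1 at -0.89 ± 0.22 and Mavs, the adaptor of cytosolic RNA sensing, at -0.97 ± 0.22. The locus on the pDC side was Slc15a4, a lysosomal transporter needed for pDC responses (0.58 ± 0.14). Without cDC replicate 1 the calls of Tlr3, Tlr1, Mavs and Slc15a4 ended, at -0.67, -0.88, -1.01 and 0.56. Without cDC replicate 2 they ended at -0.60, -0.90, -0.92 and 0.60. The calls of Mavs with flanks of 50 kb (-0.21), Tlr1 at 2-fold over input (-0.52) and Tlr3 at a mean of at least 30 counts (-0.46) were lost too. Of 23 C-type lectin loci, 4 were higher in cDCs and 1, Clec10a, in pDCs, and adjusted over the list alone 6 and 1. Clec4b2 lay at -1.39 ± 0.31 (edgeR adjusted p = 0.00665), Cd209d at -0.98 ± 0.21, Mgl2 at -0.74 ± 0.19 and Cd207, the Langerhans cell lectin, named after its values were seen, at -1.29 ± 0.34. The call of Clec4b2 was lost in the DESeq2 Wald test (adjusted p = 0.151). Those of Mgl2 and Cd207 were lost without cDC replicate 1 (log2 folds of -0.66 and -1.11), for Mgl2 also without cDC replicate 2 (-0.81). Mgl2 further lost it with flanks of 50 kb (-0.14) and by the gene span alone (-0.55).

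Of 20 chemokine and related receptor loci, 4 were higher in pDCs and 3 in cDCs, and adjusted over the list alone 5 and 3. Cxcr4, the receptor for CXCL12, lay at 0.79 ± 0.16 (edgeR adjusted p = 0.00387) and Cmklr1 at 0.66 ± 0.13 (edgeR adjusted p = 0.00292), against Cxcr6 at -0.87 ± 0.22 and Ccr1 at -0.81 ± 0.19. Named after their values were seen, S1pr1 (1.24 ± 0.31) and Cxcr2 (0.78 ± 0.20) were higher in pDCs and Cxcr5 (-0.79 ± 0.21) in cDCs. Calls ended without cDC replicate 1 for Cxcr6 (-0.82), Ccr1 (-0.82), S1pr1 (1.19), Cxcr2 (0.79) and Cxcr5 (-0.51). Without cDC replicate 2 they ended for Cxcr6 (-0.93), Ccr1 (-0.80), S1pr1 (1.30) and Cxcr2 (0.77). The Ccr1 value depended on the locus definition, at -0.09 with flanks of 50 kb, -0.08 by nearest gene and -0.47 by the gene span alone, all without a call (edgeR adjusted p = 0.460, 0.588 and 0.624). Cxcr5 lost its call with flanks of 50 kb (-0.20), at a mean of at least 30 counts (-0.51) and at 2-fold over input (-0.57), and S1pr1 at 2-fold over input (1.12).

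Known PU.1 target loci were called in both directions, 5 of 40 higher in pDCs and 3 in cDCs, with 5 and 3 also when adjusted over the list alone. Over all loci 17.6% were called, and this list did not stand apart from the others by camera (adjusted p = 0.685). Blnk, an adaptor of B cell receptor signalling, lay at 0.75 ± 0.13 (edgeR adjusted p = 0.00191), and Cebpb is described among the regulators. The scavenger receptor gene Msr1 (-0.86 ± 0.18) and the lysozyme gene Lyz2 (-0.97 ± 0.23) lay on the cDC side. Named after their values were seen, Fcer1g (0.53 ± 0.14), Coro1a (0.40 ± 0.12) and Vav1 (0.39 ± 0.13) were higher in pDCs. Without cDC replicate 1 calls ended for Cebpb (0.97), Msr1 (-0.73), Lyz2 (-0.85), Fcer1g (0.50), Coro1a (0.32) and Vav1 (0.38). Without cDC replicate 2 they ended for Fcer1g (0.56), Coro1a (0.49) and Vav1 (0.40), and without pDC replicate 1 for Vav1 (0.20). Flanks of 50 kb ended the calls of Coro1a (0.09), Fcer1g (0.31) and Vav1 (0.11), and the gene span alone those of Blnk (0.27), Fcer1g (0.32) and Vav1 (0.33). By nearest gene those of Fcer1g (0.19), Lyz2 (-0.48) and Vav1 (0.32) ended, and at 2-fold over input that of Lyz2 (-0.69). Vav1 also lost its call with library-size scaling, DESeq2 factors, abundance-trended offsets, all 5 libraries and the DESeq2 Wald test, at log2 folds between 0.37 and 0.38.

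Markers of other blood lineages were listed because a culture can hold other cells. PU.1 signal near a gene is not its expression, so these values cannot show whether such cells were present. Of 15 B cell loci, 5 were higher in pDCs and 0 in cDCs, and adjusted over the list alone 6 and 0. Blk, a kinase of the B lineage, lay at 1.29 ± 0.20 (edgeR adjusted p = 0.000678), and Pax5, the B cell commitment factor (chromosome 4, 44524748 to 44710694), at 0.95 ± 0.15 (edgeR adjusted p = 0.000988), with a region higher in pDCs within its span (44671051 to 44671360). Vpreb3 lay at 1.48 ± 0.34, with all windows shared, Bank1 at 0.54 ± 0.15 and Ms4a1, the CD20 gene, named after its values were seen, at 0.62 ± 0.20. Without cDC replicate 1 the calls of Vpreb3, Bank1 and Ms4a1 ended, at 1.44, 0.59 and 0.61. Without cDC replicate 2 they ended at 1.52, 0.48 and 0.64. With flanks of 50 kb Ms4a1 turned to -0.11 and Vpreb3 fell to 0.25 without a call. Ms4a1 also lost its call by nearest gene, with library-size scaling, no filter, both stricter filters and all 5 libraries, at log2 folds between 0.41 and 0.61. Of 18 T and NK cell loci, 2 were higher in pDCs and 0 in cDCs with either adjustment, counting adjusted over the list alone. These were Lat (2.49 ± 0.30), with 94.1% of its windows shared, and Thy1 (0.85 ± 0.26). The Thy1 call ended without cDC replicate 1 (0.89) and without cDC replicate 2 (0.80). Thy1 also lost its call by the gene span alone (1.05) and at 2-fold over input (1.08). Tbx21 lay at 1.03 ± 0.35 and Cd28 at 0.58 ± 0.21 without a call. Tbx21 gained a call without pDC replicate 2, at 1.27, and Cd28 without pDC replicate 1, at 0.87. Neither of these fits holds a spread between pDC libraries.

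Macrophage and neutrophil loci were called in both directions, 5 of 22 higher in pDCs and 3 in cDCs, and adjusted over the list alone 5 and 4. Marco, a scavenger receptor, lay at 1.25 ± 0.16 (edgeR adjusted p = 0.000227) and Ly6g at 1.97 ± 0.46, against Timd4 at -0.92 ± 0.17 and Adgre1, the F4/80 antigen, at -1.80 ± 0.34 (edgeR adjusted p = 0.00265). Mpo (0.94 ± 0.26) and Mertk (0.69 ± 0.21), named after their values were seen, and Cxcr2 were higher in pDCs and Lyz2 in cDCs. Leaving out cDC replicate 1 ended the calls of Ly6g (2.01), Mpo (0.83), Mertk (0.66), Cxcr2 (0.79) and Lyz2 (-0.85). Without cDC replicate 2 the calls of the first 4 ended as well, at 1.93, 1.05, 0.71 and 0.77. Ly6g turned to -0.30 with flanks of 50 kb, which also ended the calls of Adgre1 (-0.31, edgeR adjusted p = 0.172), Mpo (0.05) and Mertk (0.38). Adgre1 lost its call by nearest gene as well (-0.31, edgeR adjusted p = 0.282), Timd4 by the gene span alone (-0.56), Mpo at 2-fold over input (0.84) and Mertk at 2-fold over input (0.48) and at a mean of at least 30 counts (0.25). Of 15 erythroid, megakaryocyte and mast cell loci, 4 were higher in cDCs and 1 in pDCs, with the same numbers adjusted over the list alone. The stem and mast cell receptor gene Kit lay at -0.95 ± 0.20 (edgeR adjusted p = 0.00537), the platelet integrin gene Itga2b at -1.05 ± 0.22, Vwf at -0.38 ± 0.11 and Prss34, named after its values were seen, at -1.57 ± 0.46, against Tal1 at 0.54 ± 0.15. The calls of Tal1 (0.53) and Vwf (-0.35) ended without cDC replicate 1. Those of Itga2b (-0.90), Tal1 (0.55), Vwf (-0.40) and Prss34 (-1.52) ended without cDC replicate 2, and that of Prss34 (-0.85) without pDC replicate 1. Itga2b lost its call with flanks of 50 kb (-0.08), by the gene span alone (-1.33) and at 2-fold over input (-0.60). Tal1 and Vwf lost theirs by nearest gene (0.29 and -0.32), at a mean of at least 30 counts (0.45 and -0.31) and at 2-fold over input (0.45 and -0.26), and Vwf with flanks of 50 kb (-0.20).

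Of 14 non-haematopoietic loci with signal, 2 were higher in pDCs and 0 in cDCs, with the same numbers adjusted over the list alone. Tnnt2, a cardiac troponin gene, lay at 1.90 ± 0.48, and its edgeR adjusted p was 0.191 without cDC replicate 2. Ins2 lay at 1.39 ± 0.64 and Krt5 at 0.39 ± 0.25 without a call. Ins2 gained a call without cDC replicate 1, at 2.99, and Krt5 without pDC replicate 1, at 0.67. Of 20 housekeeping loci, 2 were higher in pDCs and 1 in cDCs, and adjusted over the list alone 1 and 0. Actb lay at 0.70 ± 0.14 (edgeR adjusted p = 0.00328), Rpl13a at 0.53 ± 0.16 and Gusb at -0.40 ± 0.13. Leaving out cDC replicate 1 ended the calls of Actb (0.59), Rpl13a (0.49) and Gusb (-0.43). Without cDC replicate 2 those of Rpl13a (0.58) and Gusb (-0.38) ended. Actb turned to -0.08 by the gene span alone and Rpl13a to -0.22 by the nearest gene. Rpl13a and Gusb lost their calls by the gene span alone (0.08 and -0.38), at a mean of at least 30 counts (0.38 and -0.37) and at 2-fold over input (0.54 and -0.36), and Gusb by nearest gene (-0.38), with flanks of 50 kb (-0.11) and in the DESeq2 Wald test (-0.41).

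**Figure D3:**
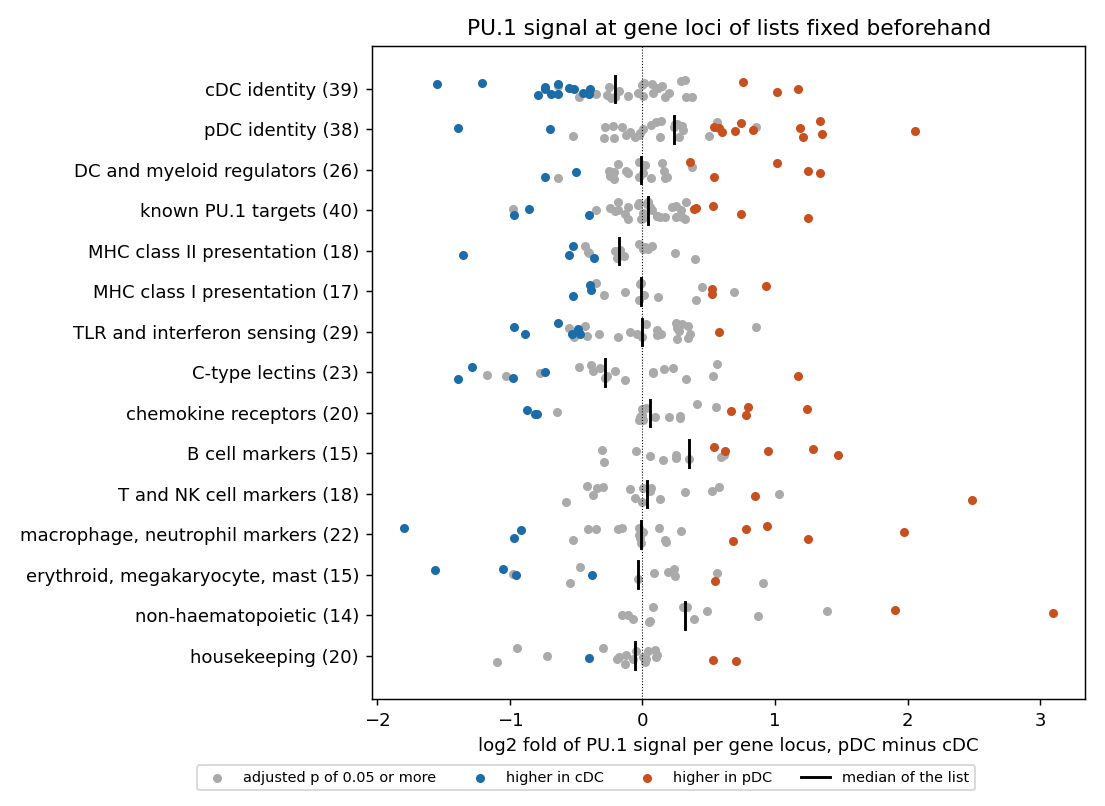
Log2 fold of PU.1 signal per gene locus (x axis, pDC minus cDC) for each list (y axis, number of measured loci in brackets), with 1 point per locus, coloured where the adjusted p was below 0.05, and a bar at the median of each list. Medians lie at -0.20 for cDC identity, 0.24 for pDC identity and 0.35 for B cell markers. With library sizes from the repeat windows the last 2 fall below 0, to -0.23 and -0.13, where the median of all loci is -0.46.

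No list as a whole stood apart from the other loci by camera with the preset correlation, where 5 of 15 lists had an unadjusted p below 0.05. The smallest adjusted p was 0.0674, for pDC identity (median log2 fold 0.24) and B cell markers (0.35), both towards pDCs. It was 0.0927 for cDC identity (-0.20) and MHC class II presentation (-0.18), towards cDCs, and for non-haematopoietic genes (0.32), towards pDCs. With library sizes from the repeat windows the medians of pDC identity, B cell markers and non-haematopoietic genes fell below 0, and relative to the median of all loci they lay at 0.24, 0.33 and 0.28. With an estimated correlation the smallest camera adjusted p was 0.632. That version takes its degrees of freedom from the 4 libraries alone, so it had little power and cannot show that lists do not differ. For B cell markers the unadjusted camera p was 0.0959 with it and 0.00508 with the preset correlation of 0.01. Their estimated correlation, -0.0509, was lower than the preset one. By fry, which asks whether the loci of a list move one way on balance, only B cell markers passed (adjusted p = 0.00821). The Fisher test of the direction of called members, chosen after seeing the data, passed no list. Its adjusted p was 0.143 for cDC identity, the smallest, 0.191 for pDC identity and 0.194 for MHC class II presentation, sensing and B cell markers. By nearest gene, pDC identity (camera adjusted p = 0.00804) and B cell markers (0.00689) passed towards pDCs and MHC class II presentation (0.0334) towards cDCs. Without cDC replicate 1, pDC identity (0.0471), B cell markers (0.0471) and non-haematopoietic genes (0.0236) passed by camera, and 0 lists passed without cDC replicate 2, pDC replicate 1 or pDC replicate 2. Over all settings tried the adjusted p of these lists lay between 0.00804 and 0.632 for pDC identity, 0.00689 and 0.632 for B cell markers, 0.0334 and 0.632 for MHC class II presentation and 0.0236 and 0.753 for non-haematopoietic genes.

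For the other lists the camera adjusted p was 0.171 for C-type lectins (median -0.28), 0.460 for housekeeping genes (-0.06), 0.557 for chemokine receptors (0.06), 0.620 for sensing (-0.01) and for erythroid, megakaryocyte and mast cell markers (-0.03), 0.658 for T and NK cell markers (0.03) and 0.685 for known PU.1 targets (0.04). It was 0.784 for MHC class I presentation, 0.803 for macrophage and neutrophil markers and 0.913 for regulators, all 3 with a median of -0.01 and means of 0.09, 0.04 and 0.08, so their median differed in sign from the mean and the test.

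The loci with the largest folds held few windows. Hfm1, a helicase of meiotic recombination (chromosome 5, 106840193 to 106926712), had a log2 fold of 3.78 ± 0.30 (edgeR adjusted p = 3.42e-05), with 6.38 and 8.85 CPM in cDCs against 137 and 72.1 CPM in pDCs. Gm46058 (4.57 ± 0.40) and Ttc13 (3.93 ± 0.33) share windows on chromosome 8. Cdcp3 (4.25 ± 0.62), Dok7 (4.02 ± 0.49), Muc5ac (3.76 ± 0.40), Lrrc15 (3.70 ± 0.60), Grm2 (3.59 ± 0.43), Brdt (3.55 ± 0.43) and Rtl1 (3.47 ± 0.43) complete the 10 on the pDC side. On the cDC side, Kif4, a kinesin gene (chromosome X, 100626065 to 100727271), had a log2 fold of -3.54 ± 0.53 (edgeR adjusted p = 0.00065), with 11.99 and 9.69 CPM in cDCs against 1.35 and 0.391 CPM in pDCs. Cstdc4 (-2.96 ± 0.39), Gm45521 (-2.89 ± 0.33), Nup85 (-2.86 ± 0.40), Olfr715b (-2.82 ± 0.49), Lgi4 (-2.76 ± 0.40), Ndufb11 (-2.69 ± 0.52), Gm44180 (-2.64 ± 0.54), Boc (-2.57 ± 0.55) and Pitpnb (-2.56 ± 0.67) followed. All windows of Gm46058, Ttc13, Lrrc15, Grm2, Gm45521, Nup85, Olfr715b, Lgi4, Ndufb11 and Gm44180 are shared with other genes. The signal of these loci therefore cannot be assigned to the gene named. The pDC libraries of Pitpnb were unequal at 0.150 and 4.30 CPM, its call was lost in the DESeq2 Wald test (adjusted p = 0.367), and it turned to 0.01 with flanks of 50 kb. Those flanks also ended the calls of Dok7, Rtl1, Gm45521, Ndufb11, Gm44180 and Boc, and the Boc call was lost without cDC replicate 2 (-2.13). Some loci that kept a call had much smaller folds in other settings, among them Nup85 (as small as -0.54), Lgi4 (-0.35), Ttc13 (1.15) and Lrrc15 (0.98). Rtl1 also lost its call by nearest gene (0.04) and Gm44180 with no filter (-0.86).

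The windows with the smallest adjusted p marked single sites. In 3 neighbouring windows on chromosome 10 (83662051 to 83662160), 13173 to 13273 bp from Appl2, the cDC libraries had 2 to 5 counts and the pDC libraries 67 to 181, with log2 folds between 5.46 and 6.06 (edgeR adjusted p = 4.68e-08). A window in the Hfm1 span (106891901 to 106891910) had a log2 fold of 4.46 ± 0.37, and a window on chromosome 4 (54714801 to 54714810), whose nearest gene, Zfp462, is 229680 bp away, had 3.91 ± 0.33. On the cDC side, 2 windows on chromosome 1 (78895951 to 78896010), 75918 and 75968 bp from Kcne4, had 80 to 109 counts in cDCs and 2 to 7 in pDCs, with log2 folds of -3.82 ± 0.42 and -3.88 ± 0.44. A pair of windows 58588 and 58638 bp from Chrm3 on chromosome 13 (-3.51 ± 0.43 and -4.08 ± 0.47) and a window in the Vipas39 span on chromosome 12 (-2.70 ± 0.32) came next. The input had 0 to 5 counts in each of these windows.

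Regions that differed lay more often far from genes than regions not called, a difference that was not tested. The best window was more than 10 kb from any gene span in 33.1% of regions higher in pDCs, 29.3% of those higher in cDCs and 26.5% of those not called. It lay inside a gene span in 53.1%, 55.2% and 54.9%.

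Relative to the cDC input, 101295 windows (35.4%) were above background in cDCs and 89783 (31.3%) in pDCs. Of the windows called higher in a cell type, 62.0% in cDCs and 58.9% in pDCs were above input there. The input had 74.6% of its counts in repeat windows, and these numbers followed the scaling. They were 7377 and 9830 with TMM factors, and, with scalings chosen after seeing the data, 3954 and 4899 with library sizes outside the repeat windows and 279918 and 262964 with library sizes from the repeat windows.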

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

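The 41111 windows, 8757 regions and 2645 loci that differed stayed within 1.5 times these counts with library-size scaling, DESeq2 factors, no count filter, all 5 libraries, abundance-trended offsets or a wider region gap, wherever these were run. So did the number of loci by the other locus definitions, but the loci themselves changed. Of the 2645, 1704 were also called with flanks of 50 kb, 1741 by nearest gene and 1429 by gene span alone. Among these, 25, 7 and 2 had the opposite direction. Loci tested were 17787, 13812 and 11501 in the same order, against 14998. Other settings moved the counts, and the cause was not tested except where the setting itself removes windows or libraries or asks for a larger fold. Differing windows were 9111 (6545 higher in pDCs, 2566 in cDCs) in the DESeq2 Wald test, 15718 of 75839 at a mean of at least 30 counts, 19051 of 111153 at 2-fold over input, 18827 for a fold of at least 1.5 and 20556 with library sizes from the repeat windows. Differing loci were 1714 at a mean of at least 30 counts, 469 for a fold of at least 1.5 and 105 with library sizes from the repeat windows. With each library left out in turn, the lone sample being assumed to vary like the other cell type, they ranged from 12511 to 67073 windows, 3031 to 15662 regions and 883 to 5402 loci. Of 15 lists, 0 passed by camera, 1 by fry, 3 by nearest gene and between 0 and 3 with a library left out. Windows above input were 7377 in cDCs and 9830 in pDCs with TMM factors, 3954 and 4899 with library sizes outside the repeat windows and 279918 and 262964 with sizes from the repeat windows, against 101295 and 89783, and stayed within 1.5 times with a library left out.

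With the replicate block there were 42844 windows (23183 higher in pDCs, 19661 in cDCs), 9680 regions, 2383 loci and 0 lists, and 9 of 92 named calls were lost, among them Vav1, Stat5b, Ms4a1, H2-Aa, Psmb9, Mertk, Rpl13a and Gusb (edgeR adjusted p between 0.0505 and 0.0734), and 1 was gained, Cd28 (0.56, edgeR adjusted p = 0.0477). The labels do not say what the replicate numbers share, and the deviations of equal numbers from their cell type's mean had a correlation of 0.0133.

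Over 109 named loci and all settings, 1613 values kept direction and side of the threshold, 342 lost the call, 16 gained one and 16 changed direction. The direction was compared only where the locus was called in at least 1 of the 2 settings. With flanks of 50 kb the log2 fold was 0.32 for Irf8, -0.0806 for Irf4, 0.0140 for Pitpnb, -0.0557 for Clec10a, -0.30 for Ly6g, -0.36 for Tap2, -0.34 for Psmb8 and -0.11 for Ms4a1. By nearest gene it was -0.12 for Irf4, -0.22 for Rpl13a and -0.87 for Tap2, and by gene span alone -0.0795 for Actb and -0.88 for Tap2. With library sizes from the repeat windows, where the median of all loci was -0.46, it was -0.11 for Stat5b, -0.0568 for Coro1a and -0.0284 for Vav1. The causes were not tested.

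Not run were TMM on background bins, the GC correction with and without the block, loci within 2 kb of a TSS, the nearest TSS and the sequence motifs, since the sources used here give no genome sequence, strand or unselected windows. At these library totals and 2 libraries per cell type, 7.5% of simulated 2-fold changes were recovered among windows and 64% among loci. The simulation used independent windows, a constant dispersion and few changed items, so these shares need not hold in the data. What depth alone limits was not tested.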

Other observations

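Some genes held sites that differed in opposite directions. Of 4814 loci with at least 1 called region, 560 held regions of both directions. At Runx2, 2 regions were higher in cDCs (44571001 to 44571160 and 44613751 to 44613910 on chromosome 17, log2 folds of -1.99 ± 0.49 and -2.45 ± 0.66 at the best windows) and 2 in pDCs (44711251 to 44711410 and 44812801 to 44813060, 2.29 ± 0.50 and 2.77 ± 0.62). At Spi1, 2 regions were higher in cDCs (91080801 to 91081460 and 91084551 to 91084910 on chromosome 2, -1.28 ± 0.29 and -1.46 ± 0.34), and 1 in pDCs (91096101 to 91096160, 1.68 ± 0.55). Zfp366 held a region higher in cDCs (99187501 to 99187860 on chromosome 13, -1.502 ± 0.267) and 2 higher in pDCs (1.95 ± 0.50 and 3.41 ± 0.68). Zeb2 held 1 of each, with -1.81 ± 0.41 inside the gene span (45049401 to 45049610 on chromosome 2) and 1.53 ± 0.29 at 1.65 kb outside it.

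Both tests that follow were chosen after the result was seen, and they replaced an earlier comparison of mixing shares and an earlier way of matching windows. In regions higher in pDCs replicate 1 exceeded replicate 2 in 79.3%, and in regions higher in cDCs in 22.7%, so pDC replicate 2 lay closer to the cDC libraries. Mixing of cDC chromatin as the whole cause would leave 1 ratio of replicate 2 to replicate 1 at strong and weak unchanged windows, but the median log2 ratio at the 3132 strong ones minus that at the 89912 weak ones was -0.228 (95% interval -0.245 to -0.213, against -0.0699 for the cDC pair). A larger share of unenriched chromatin as the whole cause would shift windows of 1 pDC level alike, but the median log2 ratio in 2273 regions higher in cDCs exceeded that of unchanged windows matched on level by 0.518 (95% interval 0.453 to 0.583). Each interval came from resampling windows of the same libraries as if they were independent, although neighbouring windows can share reads. It can thus be too narrow and does not measure the spread between libraries. Within these limits the values argue against either as the whole cause. A combination of both and a biological difference in the make-up of the 2 pDC cultures were not tested and stay open.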
